A study of Oryza sativa with 12 samples.

How the data were processed

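Rice plants were grown, per the labels, in sterile magenta boxes on half-strength Murashige and Skoog medium with 0.4% agar, at 27 °C and a 12 h photoperiod. On day 7 the wild-type control plants were moved to a container with a hypotonic solution made with tap water, and the labels name no such move for the knockout plants. Per the submitters' processing notes, reads were handled with Trimmomatic, FastQC, HISAT2, Cufflinks and Cuffdiff on genome build IRGSP-1.0, with no versions, options or annotation release given. The letters of the knockout lines are given opposite ways in the sample titles and the source names. The titles were followed here, and each result given for 1 line or for the difference between the lines belongs to the other letter if the source names are right.

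The values used were those of the authors' deposited Cuffdiff table, which covers 37672 merged loci and 6 pairwise comparisons of the 4 groups. The authors' deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), 1 value per group over its 3 replicates, scaled between libraries by a method not stated. The deposited fold changes are log2 ratios of these FPKM and are infinite where 1 of the groups is listed at 0. A score, the Cuffdiff test statistic, was deposited for each tested locus, and is the log2 ratio over its standard error. The deposited p-value and q-value columns were related by Benjamini-Hochberg adjustment over the 108602 tests of all 6 comparisons together, which gave the deposited q to within 5.27e-07. The smallest p in the authors' deposited table was 5e-05, shared by 21471 tests. Values per replicate and sequencing depth were not available, so no standard deviation between replicates is given, no replicate was left out in turn, and no floor for a value of 0 is stated.

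A locus was called where the deposited q was under 0.05 and the table lists the test as done, and the direction was taken from the group values. The error printed beside a log2 ratio is the standard error implied by the deposited test statistic, that is, the log2 ratio divided by the statistic. Squared errors of this kind added up over pairs of groups to within 1.75e-05 of the sum over 17512 loci, so an error could be solved for each group. The normal deviate of the deposited p, for p from 0.001 to 0.5, was a median 1.75 times the statistic, close to the square root of the 3 replicates (1.73). At the typical locus the deposited p thus treats a ratio as more precise than the implied error does. Some loci near 0 in 1 group went the other way. In line a against 5-day wild type Os01g0537250 had a log2 ratio of 8.51, an implied error of 2.41 and a Cuffdiff p of 0.240. Both readings were run, and the deposited q was kept for the calls because that choice was written before the data were examined. An implied error exists only for a finite ratio, so loci with a group listed at 0 drop out of tests that use it. The merged locus with the largest value in 12-day wild type, 7225430 FPKM, spans 39 bases and was not used.

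Of the loci, 36019 hold 1 annotated gene, 988 hold several and 665 (1.77%) hold none. The table carries locus identifiers without names or descriptions, so symbols came from gene lists written by locus. Themes of the main lists were fixed before the data were examined, with 80 members, of which 77 were kept. Members of the other themes, and further members of themes already begun (8 of the 12 kept jasmonate and TIFY loci, among them all TIFY genes, and CHT1), were filled in by locus after the table had been opened, 147 written and 92 kept, so those lists were not blind to the table's identifiers. Late members were kept only where RefSeq gave the symbol at the same place, which dropped 55, whereas earlier members absent from RefSeq were kept. This uneven rule left 4 of 12 WRKY loci and 12 of 34 photosynthesis loci. Of the 80, 54 carried the same symbol at the same relative place in the RefSeq annotation of assembly ASM3414082v1, 23 had symbols absent from it, 2 were dropped because the symbol lay elsewhere, and 1 was not in the table. Same place means the same chromosome, with relative positions within 0.1 of its length, which is a loose check. The alias PAL was accepted for each of PAL1, PAL2 and PAL3. A further 3 lists (chlorophyll synthesis, chlorophyll breakdown, circadian clock) were written after values had been seen and were adjusted as a family of their own. Lists that could be made only from descriptions, such as laccases, peroxidases and ribosomal proteins, were not analysed here.

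The genes named were chosen by a rule fixed before the data were examined. It took OsC3'H1, and for each of 3 sets (knockout against 12-day wild type in both lines, knockout against both wild types in both lines, 12-day against 5-day wild type) the 10 named loci with the largest rise and the 10 with the largest fall. Ranks followed the smallest absolute log2 ratio of the comparisons concerned, over called loci above 0 in each compared group and with an FPKM of at least 5 in 1 of them. For line b against line a it took 5 in each direction. From each list it took up to 4 members called in both lines against 12-day wild type, highest mean FPKM first, or the most expressed member where none was called. Only loci with a name could enter, which are the 165 kept in the lists, so these are the largest changes among list members and not among all loci. Genes outside the rule that complete a count (MCM2, CDKB1-1, PR1b, OSH15, 4CL2, CCR19, MAS) were chosen after their values were seen.

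Lists were tested with Fisher's exact test, two-sided, of called members against all other tested loci, for each direction, and adjusted by Benjamini-Hochberg over the lists and directions of a comparison. Genes of a list are not independent and no set test with an estimated correlation could be run without values per library, so these p-values are too small. List medians of the log2 ratio were ranked among 10000 random lists of the same size matched on mean FPKM. A list is tested in the text where at least 4 members were tested, or 3 for a list given by loci only. Where a comparison shares a control, 100 draws of unchanged groups gave the value expected from sharing alone. Their errors were the implied errors divided by 1.75, on the scale of the deposited p. The draws for the place of the knockout lines between the wild types were added after its values were seen, and used the implied errors undivided. In simulated data for line a against 12-day wild type, 15996 loci were drawn with the implied errors divided by 1.75. Called were 76 of 100 loci changed by a log2 of 1, 97 of 100 changed by a log2 of 2, and 5 of 15796 unchanged loci (0.0317%). Few loci were changed there, so the cut-off on p was stricter than in the data. The 0.0317% is therefore no rate of false calls for the deposited table. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.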

Results

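RNA sequencing measured transcripts in whole aerial parts of rice, cultivar Nipponbare, in 12 samples forming 4 groups of 3 biological replicates. The groups were wild type at 5 days, wild type at 12 days, and 12-day plants of 2 knockout lines, a and b, of OsC3'H1, the lignin pathway gene for p-coumaroyl ester 3-hydroxylase. The authors' deposited table lists 25605 loci above 0 in 5-day wild type, 26144 in 12-day wild type, 27066 in line a and 27134 in line b. The numbers at 1 FPKM or more were 20882, 21295, 22112 and 22152 in the same order. Median group errors implied by the deposited test statistics were 0.225, 0.231, 0.225 and 0.225 on the log2 scale. The depth of each library is unknown, as the table holds no counts, and each group has 1 value over its 3 replicates.

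The first question was how far the transcript of the targeted gene was lowered. OsC3'H1 (CYP98A4, Os05g0494000, IRGSP-1.0 chromosome 5, 24271089 to 24275162) fell in both lines. In the authors' deposited table it stood at 65.7 FPKM in 5-day wild type, 53.1 in 12-day wild type, 10.7 in line a and 12.9 in line b. Against 12-day wild type this was 4.96-fold lower in line a (log2 -2.31, implied error 0.28) and 4.13-fold lower in line b (log2 -2.05, implied error 0.26). Against 5-day wild type the deposited values were 6.14-fold and 5.12-fold lower. The lines did not pass the test against each other for this gene (log2 0.26). A transcript level does not show whether a functional protein was made.

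The comparison of each line with 12-day wild type addresses what differed between the knockout lines and wild-type plants of the same age. Photosynthesis genes were lower in both lines, 12 of 12 tested, and pathogenesis-related genes were higher, 5 of 5 tested. RBCS (Os12g0274700), the small subunit of Rubisco, went from 23720 FPKM in 12-day wild type to 1507 in line a and 1452 in line b in the authors' deposited table, 15.7-fold and 16.3-fold lower (log2 -3.98 and -4.03, implied error 0.32 each). SALT (Os01g0348900), a salt-induced mannose-binding lectin, went from 112 FPKM to 7955 and 8394 in that table, 71.3-fold and 75.2-fold higher (log2 6.16 and 6.23, implied errors 0.27 and 0.29). CHT1 (Os06g0726200), a chitinase that degrades fungal wall chitin, rose 24.6-fold and 31.0-fold (log2 4.62 and 4.96, implied error 0.27 each) by the deposited values. NIA1 (Os08g0468100), a nitrate reductase, fell from 63.2 FPKM to 2.65 and 4.18 (log2 -4.58 and -3.92, implied errors 0.41 and 0.33).

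By the deposited q, 8225 of 18343 tested loci were called in line a (3911 higher, 4314 lower) and 8533 of 18416 in line b (4084 higher, 4449 lower). Changes of at least 2-fold were called at 3816 and 4036 loci. Both lines were called in the same direction at 7180 loci, 3338 higher and 3842 lower, and in opposite directions at 2. Independent calls would give 840 shared higher and 1062 shared lower loci, and unchanged groups sharing the 12-day control gave a mean of 52.3 and a maximum of 72 in 100 draws. Genotype and growth medium differ together in this comparison, because only wild-type plants are described as moved on day 7. With a test that takes the implied error as deposited, 4276 loci were called in line a and 4437 in line b.

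**Figure D1:**
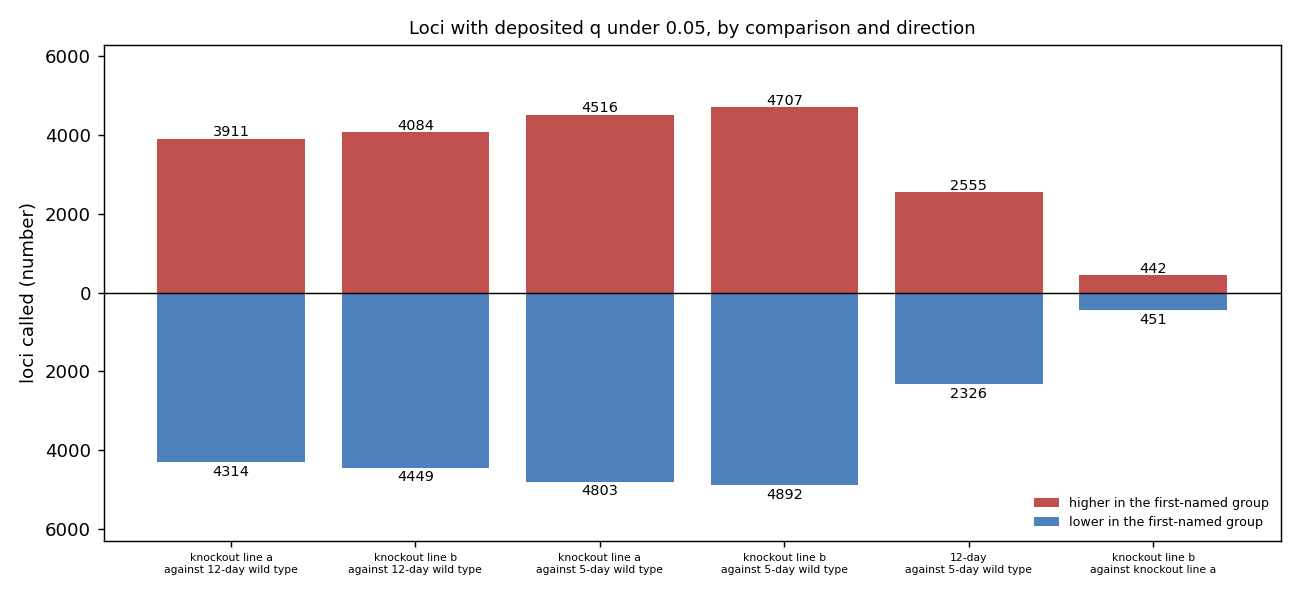
Loci with a deposited q under 0.05 in each of the 6 comparisons (vertical axis, number of loci), with loci higher in the first-named group above the zero line and loci lower in it below. Each knockout line was called against either wild type at 8225 to 9599 loci, the wild types against each other at 4881, and the lines against each other at 893.

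Across genes, the log2 ratios of the lines against 12-day wild type had a Pearson's r of 0.960 and a Spearman's rho of 0.938 over 15946 loci. Genes are not independent replicates, and the shared control alone gave an r of 0.713 across genes and a covariance of 0.0967 in simulations of 17189 unchanged loci, beside the observed 0.960 and 0.776. The simulated errors were on the scale of the deposited p, and the larger implied errors would give a larger covariance. Pairing line a against 12-day with line b against 5-day wild type, which share no library, gave an r of 0.787 and a rho of 0.769, and the reverse pairing gave 0.769 and 0.763.

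Photosynthesis genes fell in both lines against 12-day wild type, 12 of 12 tested, with list medians of -2.69 in line a and -2.97 in line b (Fisher's exact test, adjusted p = 1.30e-06 and 1.80e-06). The list was drawn up for photosystems and light harvesting, and its kept members were 7 photosystem or antenna genes (PSBW, PSAH, PSB28, CAB1R, CAB2R, LHCB2, LHCB3), PETE and LFNR1 of electron transport, and RBCS, RCA and FBPase of carbon fixation. RCA (Os11g0707000), which activates Rubisco, went from 9116 FPKM to 1046 and 806 in the authors' deposited table (log2 -3.12 and -3.50, implied errors 0.36 and 0.35). PETE (Os06g0101600), plastocyanin, had deposited log2 ratios of -2.79 and -3.08 (implied error 0.22 each), and PSBW (Os01g0773700), a photosystem II subunit, -2.88 and -3.20 (implied error 0.21 each). LFNR1 (Os06g0107700), the leaf ferredoxin-NADP reductase, was deposited at -2.80 and -3.01, and FBPase (Os03g0267300), an enzyme of the Calvin cycle, at -2.71 and -2.87 (implied error 0.46 each). CAB1R, a chlorophyll-binding antenna protein, had the smallest deposited change of the list (log2 -0.85 and -0.87).

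Nitrogen assimilation genes were lower in 4 of 6 tested in both lines, and the list did not pass its test (Fisher's exact test, adjusted p = 0.166 in line a and 0.170 in line b). It passed with a 2-fold minimum (adjusted p = 0.0166 and 0.0206, Fisher's exact test) and with the implied error as deposited (0.0201 and 0.0229). FD-GOGAT (Os07g0658400), a glutamate synthase, stood at 812 FPKM in 12-day wild type and at 105 and 106 in the knockouts in the authors' deposited table (log2 -2.95 and -2.94). GS2 (Os04g0659100), plastid glutamine synthetase, went from 2087 to 321 and 271 FPKM (log2 -2.70 and -2.94), and AMT1;1, an ammonium transporter, had deposited ratios of -1.14 and -1.27. GS1;1, cytosolic glutamine synthetase, rose in both (log2 0.53 and 0.28). Cell cycle and DNA replication genes fell, 11 of 13 in each line with medians of -0.94 and -0.90 (Fisher's exact test, adjusted p = 1.33e-04 and 1.18e-04). PCNA, the replication clamp, went from 122 FPKM to 49.1 and 50.9 in the authors' deposited table (log2 -1.32 and -1.26), and CDKB2-1, a mitotic kinase, CYCB1-1, a mitotic cyclin, and MCM3, a subunit of the replicative helicase, had ratios of -0.93 and -0.90, -1.11 and -0.84, and -0.86 and -1.04. MCM2 and CDKB1-1 were not called. With a change of at least 2-fold required, the cell cycle list in line b no longer passed (adjusted p = 0.252, Fisher's exact test).

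Pathogenesis-related proteins rose, 5 of 5 in each line with medians of 4.62 and 4.96 (Fisher's exact test, adjusted p = 0.00674 and 0.00616), and 5 of 5 when adjusted over the list alone. PBZ1 (Os12g0555500), a probenazole-induced protein of the PR10 family, went from 4.48 FPKM to 194 and 330 in the authors' deposited table (log2 5.44 and 6.20, the latter with an implied error of 1.07). PR5 (Os12g0628600), a thaumatin-like protein, had deposited ratios of 3.15 and 3.76 (implied errors 0.36 and 0.35), and PR1a (Os07g0129200), a marker of induced defence, 5.82 and 6.11 with wide implied errors of 1.81 and 1.80. The 4 WRKY factors kept of 12 written, regulators of defence transcription, rose in both lines (medians 2.59 and 2.72, Fisher's exact test, adjusted p = 0.0190 and 0.0222). WRKY62 (Os09g0417800) had deposited ratios of 4.41 and 4.12 (implied error 0.99 each), WRKY71 2.62 and 3.01, WRKY24 2.56 and 2.43, and WRKY76 2.23 and 1.43.

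Jasmonate synthesis genes and TIFY repressors, which restrain jasmonate responses, rose at 6 of 8 tested in line a and 9 of 9 in line b (medians 0.79 and 0.99, Fisher's exact test, adjusted p = 0.0190 and 2.96e-05). The counts adjusted over the list alone were 7 and 9. TIFY11C (Os03g0180900) went from 2.01 FPKM to 22.8 and 27.5 in the authors' deposited table (log2 3.50 and 3.77), and TIFY10C (Os09g0439200) from 9.60 to 54.2 and 56.7 (log2 2.50 and 2.56). TIFY10B had deposited ratios of 0.89 and 0.99, AOC, allene oxide cyclase, 0.57 and 0.55, and OPR7, an oxophytodienoate reductase, 0.69 and 0.65. With at least a 2-fold change required, the list no longer passed in line a or line b (Fisher's exact test, adjusted p = 0.661 and 0.0612).

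**Figure D2:**
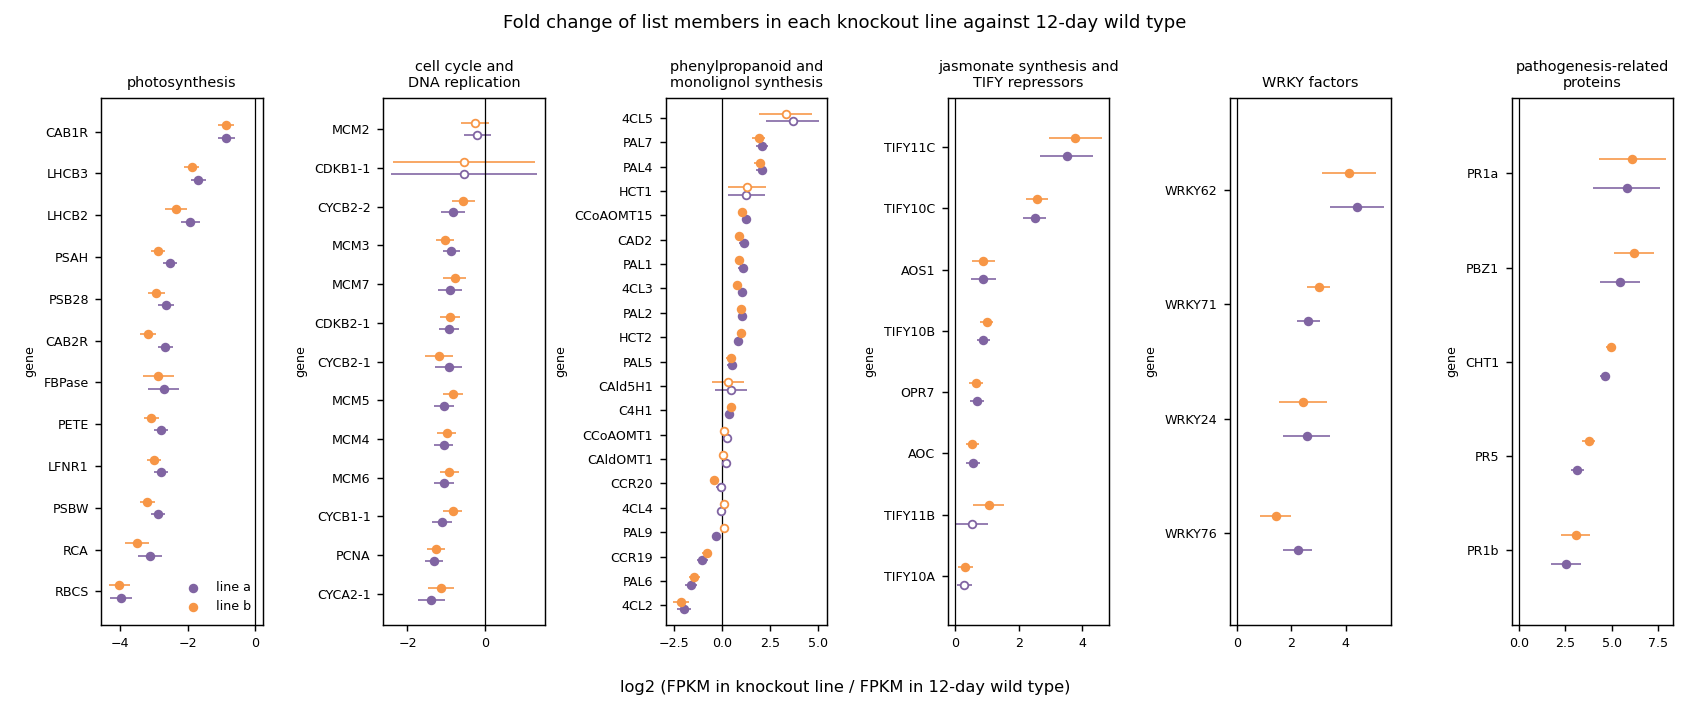
Log2 ratio of each tested member of 6 gene lists in line a and line b over 12-day wild type (horizontal axis, log2 of FPKM over FPKM; vertical axis, genes), filled where called, open where not, with bars of 1 implied standard error. The photosynthesis members lie at -0.85 or lower, and the pathogenesis-related members at 2.52 or higher.

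Dehydration and LEA proteins were higher in both lines at 3 of 5 tested, which did not pass (Fisher's exact test, adjusted p = 0.287 and 0.305) except with the implied error as deposited (0.00342 and 0.0475) and, in line a, with a 2-fold minimum (0.0468). Among them LEA3 (Os05g0542500), a late embryogenesis abundant protein, went from 6.05 FPKM to 94.0 and 54.2 in the authors' deposited table (log2 3.96 and 3.16, implied errors 0.49 and 0.50). Of the low oxygen genes, 2 rose and 1 fell among the 4 tested in both lines, and the rises did not pass as a list (Fisher's exact test, adjusted p = 0.577 and 0.345) except with the implied error as deposited (0.0208 and 0.0125). HB1 (Os03g0233900), a haemoglobin induced by low oxygen, had deposited ratios of 3.76 and 3.61, and ADH1, alcohol dehydrogenase, 0.67 and 0.68, whereas PDC2, pyruvate decarboxylase, was lower (-0.68 and -0.53). Iron acquisition genes were higher at 2 of 3 tested, 2 in each line when adjusted over the list alone, without passing (Fisher's exact test, adjusted p = 0.384 and 0.345). NAAT1 (Os02g0306401), of phytosiderophore synthesis, went from 2.12 FPKM to 24.8 and 29.8 (log2 3.54 and 3.81) in the authors' deposited table, and NAS1, nicotianamine synthase, listed at 0 in both wild types, stood at 11.2 and 9.39. Diterpenoid phytoalexin genes, which make antimicrobial compounds, rose at 3 of 4 tested in line a and 5 of 9 in line b, also when adjusted over the list alone (Fisher's exact test, adjusted p = 0.166 and 0.170, and 0.0231 and 0.0117 with a 2-fold minimum). A group was listed at 0 for 3 of those 4 loci and for 5 of those 9, and such infinite ratios pass any fold minimum.

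Lists with too few members tested in both lines are given by gene, and none passed its test in either line. SUS1, a sucrose synthase, fell (log2 -1.30 and -1.21) and SUS2, another, rose (0.48 and 0.61), the starch and sucrose members tested in both lines, each in a merged locus of the authors' deposited table. HSP17.9A, 1 of 3 heat shock genes tested in both, rose (1.39 and 1.09). KS1 of gibberellin synthesis (-0.70 and -0.77) and SPX1 of the phosphate starvation response (-0.74 and -0.82) fell, out of 3 and 2 tested, by the deposited values. ACO1, the ethylene synthesis gene tested, was called lower in line a and not in line b. Of markers for other tissues, LSI1, a silicon transporter of roots, rose (1.50 and 1.60). The meristem factors OSH1 and OSH15 were called in line a and not in line b, where the deposited values were 5.00 and 4.64 FPKM beside 3.18 and 2.39 in 12-day wild type, and both were called higher in both lines against 5-day wild type, where they are listed at 0. No seed storage gene was tested, GLUA2 being deposited at 2.41 to 3.22 FPKM.

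Expression of the lignin pathway around the targeted step was the next question. Genes of phenylpropanoid and monolignol synthesis, which make lignin precursors, were called in both lines against 12-day wild type at 13 of 21 loci, 10 higher and 3 lower. PAL1 (Os02g0626100), phenylalanine ammonia-lyase at the pathway's entry, went from 673 FPKM to 1425 and 1253 in the authors' deposited table (log2 1.08 and 0.90, implied error 0.25 each). PAL2, in a merged locus, had deposited ratios of 1.02 and 0.99, CCoAOMT15, a caffeoyl-CoA methyltransferase, 1.22 and 1.04, and 4CL3, a coumarate-CoA ligase, 1.03 and 0.77. PAL7 (Os05g0427400), of the same family as PAL1, had deposited ratios of 2.08 and 1.89. The 3 lower members were PAL6, 4CL2 and CCR19, the last a cinnamoyl-CoA reductase, with deposited ratios of -1.63 and -1.46, -1.99 and -2.16, and -1.04 and -0.79. In each line alone 10 were higher and 4 lower, the same numbers as when adjusted over the list alone, and the list did not pass (Fisher's exact test, adjusted p = 0.0503 in line a and 0.0926 in line b). It passed with q under 0.01 (Fisher's exact test, adjusted p = 0.00644 and 0.00892), with the implied error as deposited (0.00112 and 0.00875) and, in line a, with a 2-fold minimum (0.0226). Its medians of 0.49 and 0.48 lay at percentiles 99.96 and 99.95 of matched random lists.

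Flavonoid synthesis genes, which share the pathway's first steps, were lower at 3 of 3 tested in each line, also when adjusted over the list alone, without passing as a list (Fisher's exact test, adjusted p = 0.0854 and 0.0926). It passed with q under 0.01 (Fisher's exact test, adjusted p = 0.0432 and 0.0482) and, in line b, with the implied error as deposited (0.0163). CYP75B3 (Os10g0320100), flavonoid 3'-hydroxylase, went from 58.3 FPKM to 5.26 and 3.89 in the authors' deposited table (log2 -3.47 and -3.91, implied errors 0.35 and 0.40). CHS1, chalcone synthase, was deposited at -2.01 in both lines (implied error 0.21 in line a), and CHI, chalcone isomerase, at -0.54 and -0.62. None of the 5 primary wall cellulose synthase genes was called in either line, 0 also when adjusted over the list alone, and CESA1, the most expressed, had deposited ratios of -0.05 (implied error 0.24) and -0.12. Of 4 secondary wall cellulose synthase genes CESA9 was called (0.47 and 0.38), 1 also when adjusted over the list alone. Among 4 secondary wall transcription factors tested in both lines, MYB58/63, an activator of lignin genes, rose (1.43 and 0.97) and SWN2, a NAC switch of secondary walls, fell (-1.30 and -1.55), 1 up and 1 down when adjusted over the list alone.

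Comparing the lines with both wild types asks which changes hold whichever wild type serves as control, before or after the move to another medium. SALT, CHT1, NAAT1, TIFY11C and WRKY71 led the named genes that rose against both, and RBCS, CYP75B3, CAB2R, PSBW and LFNR1 those that fell. Against 5-day wild type SALT had deposited log2 ratios of 5.46 in line a and 5.54 in line b, CHT1 5.48 and 5.81, NAAT1 5.65 and 5.91, TIFY11C 4.30 and 4.57, and WRKY71 2.51 and 2.89. RBCS had deposited ratios of -3.74 and -3.79, CYP75B3 -2.69 and -3.12, CAB2R, an antenna protein, -4.29 and -4.81, PSBW -2.37 and -2.69, and LFNR1 -2.32 and -2.53. TIFY10C, HB1, WRKY24, WRKY76 and PAL7 also rose against 5-day wild type, from 1.35 for PAL7 to 3.76 for TIFY10C in line a of the authors' deposited table. PETE, PSAH, FD-GOGAT, PSB28 and FBPase fell against both wild types.

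Against 5-day wild type, 9319 of 18320 loci were called in line a and 9599 of 18397 in line b, 8305 of them in both lines in the same direction. The intersection over both wild types held 5604 loci, 2620 higher and 2984 lower, and 2367 of these changed at least 2-fold in all 4 comparisons. A further 107 loci were called in opposite directions against the wild types, and 930 of 17661 were called against 12-day wild type in both lines and against 5-day wild type in neither. With the implied error as deposited, 5223 loci were called in line a and 5533 in line b against 5-day wild type, and 2993 over both lines and both wild types. AMT1;1 was of the first kind, with deposited log2 ratios of 0.63 and 0.49 against 5-day wild type. LSI1 was also reversed, at -0.71 and -0.62. Age differs between the knockout lines and this control, and each line was compared with the same 3 control libraries.

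Of the lists, photosynthesis genes fell at 12 of 12 against 5-day wild type (medians -2.34 and -2.65, Fisher's exact test, adjusted p = 4.80e-06 and 5.69e-06) and cell cycle genes at 12 of 13 (medians -1.18 and -1.05, adjusted p = 2.37e-05 and 2.79e-05). Jasmonate and TIFY genes rose at 8 of 8 and 9 of 9 (Fisher's exact test, adjusted p = 2.08e-04 and 7.16e-05), the former not with a 2-fold minimum (adjusted p = 0.0904). Phenylpropanoid genes rose at 13 of 21 in line a (Fisher's exact test, adjusted p = 0.00365, and 1.000 with a 2-fold minimum) and at 11 of 21 in line b (adjusted p = 0.0894, and 0.00874 with q under 0.01 and 0.0276 with the implied error as deposited), and these were also the counts adjusted over the list alone. The difference between the lines for this list was not tested. WRKY factors rose at 3 of 4 loci, WRKY62 not being called (deposited log2 3.92 and 3.64), with 4 of 4 called when adjusted over the list alone, and did not pass as a list (Fisher's exact test, adjusted p = 0.187 and 0.192) except with the implied error as deposited (0.00335 and 0.00408). Pathogenesis-related proteins rose at 3 of 5 and did not pass as a list (Fisher's exact test, adjusted p = 0.306 and 0.316) except with that error (0.0147 and 0.0198), with PR1a and PR1b listed at 0 in 5-day wild type and PBZ1 (deposited q = 0.303 in line a) and PR5 not called. That pass covers only the 3 members with a finite ratio. It leaves out PR1a and PR1b, which the deposited q called, and includes PBZ1 and PR5. The medians of the 3 members above 0 in 5-day wild type were 6.75 and 7.37, at percentiles 99.94 and 100 of matched lists. Phytoalexin genes rose at 2 of 4 in line a (Fisher's exact test, adjusted p = 0.603) and at 7 of 9 in line b (adjusted p = 0.0179). A group was listed at 0 for 2 of those 4 loci and for 6 of those 9. With the implied error as deposited only 3 of the 9 had a finite ratio to test (Fisher's exact test, adjusted p = 1.000), so that setting does not decide the call in line b.

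**Figure D3:**
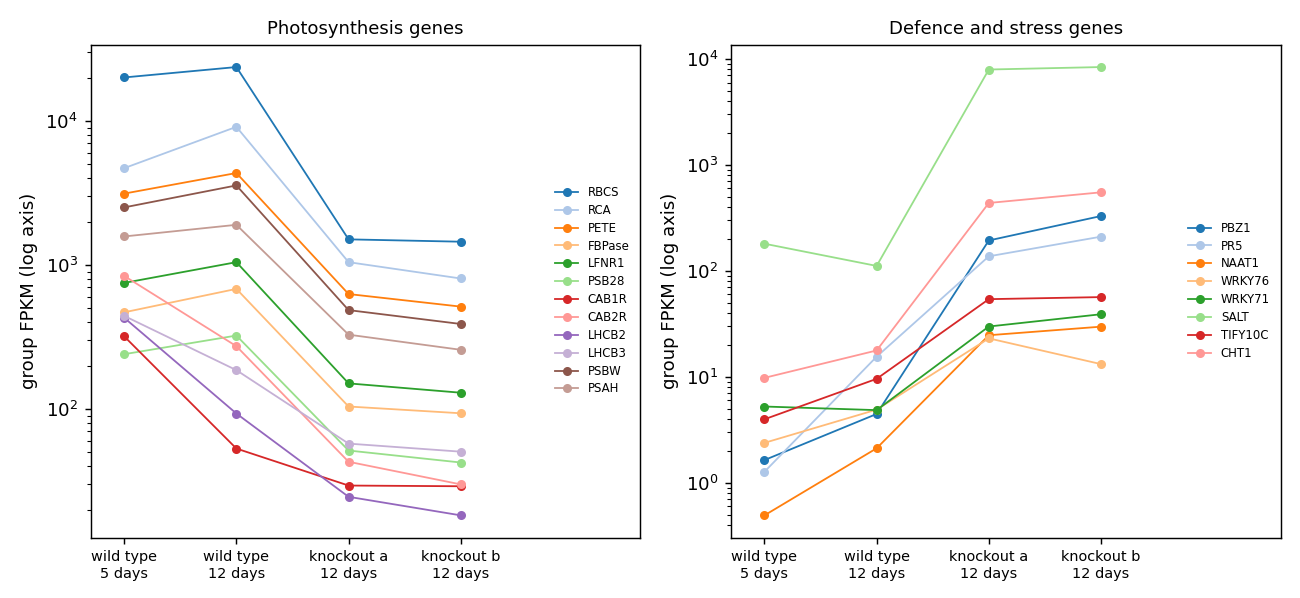
Deposited FPKM per group (vertical axis, log scale; 1 value per group over 3 replicates, no error bars) of photosynthesis genes and of 8 defence and stress genes, with lines joining the groups of one gene. RBCS stands at 20083 and 23720 in the wild types and at 1507 and 1452 in the knockout lines, and SALT at 181, 112, 7955 and 8394 in the same order of groups.

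The wild types compared at 12 and 5 days ask what changes with age and the move to another medium without the knockout. Of the photosynthesis genes the 4 lower at 12 days were antenna genes, and 4 of 6 nitrogen genes were higher, with neither list past its test. CAB1R (Os09g0346500) went from 319 to 53.1 FPKM in the authors' deposited table (log2 -2.59, implied error 0.21), LHCB2, a photosystem II antenna protein, from 430 to 92.9 (log2 -2.21), CAB2R from 840 to 273 (log2 -1.62) and LHCB3 from 443 to 186 (log2 -1.25). NIA1 rose from 17.0 to 63.2 FPKM (log2 1.90, implied error 0.22) and AMT1;1 from 21.0 to 71.2 (log2 1.77) by the deposited values. SWN2 had the largest rise among the named genes (deposited log2 2.27, implied error 0.81).

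In this comparison 4881 of 17250 tested loci were called, 2555 higher and 2326 lower at 12 days, and 1203 changed at least 2-fold. Of these 1203, 885 were higher. With the implied error as deposited 1115 loci were called, 67.8% of them higher. PAL6 (1.39), TIFY10C (1.27), RCA (0.95), CHT1 (0.86), KS1 (0.79), CYP75B3 (0.78) and SPX1 (0.74) were the other named rises in deposited log2 ratio. LSI1 (-2.22), KAO of gibberellin synthesis (-1.88), PAL4 (-1.34), GS1;2 (-1.07), PAL7 (-0.73) and SALT (-0.70) were the other named falls. No main list passed its test between the wild types, except photosynthesis genes among the lower loci with a 2-fold minimum (Fisher's exact test, adjusted p = 0.00230) or the implied error after median-centring (0.00336). These genes were split, 6 higher and 4 lower of 12, phenylpropanoid genes stood at 3 higher and 7 lower of 20, and nitrogen genes at 4 higher and 1 lower of 6. OsC3'H1 itself was lower at 12 days (deposited log2 -0.31).

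The same genes place the knockout lines on a scale from 12-day wild type (0) to 5-day wild type (1). NIA1, which was higher at 12 days, stood below both wild types in the knockouts, while AMT1;1 stood between them at 32.4 and 29.5 FPKM in the authors' deposited table. CAB2R and LHCB2, which were lower at 12 days, were lower still in the knockouts, at 43.0 and 29.9 FPKM and at 24.5 and 18.2 FPKM in the deposited values. Over genes called between the wild types with at least a 2-fold change, the median place was 0.450 in line a (1177 loci, quartiles -0.234 and 1.05) and 0.425 in line b (1175 loci, quartiles -0.215 and 1.09). The 12-day values enter both terms of this ratio, and unchanged knockout groups gave a mean median of 0.137 and 0.138 in 100 draws, with a highest of 0.158 and 0.159. The shares on the 5-day side, 67.8% and 68.5%, did not exceed those drawn for unchanged groups (means 69.2% and 69.1%). These draws added error to wild-type differences that already hold it, with errors larger than those behind the calls. They also changed no locus in the knockouts, so they do not settle what median or share would be expected here. Over all genes called between the wild types the median was 0.0467 in line a and 0.0423 in line b.

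Line b against line a tests whether the knockout lines differ. Genes of diterpenoid phytoalexin synthesis were higher in line b at 7 of 9 tested, and dehydration and LEA proteins lower at 3 of 5. KSL7 (Os02g0570400), a kaurene synthase-like cyclase, stood at 4.33 FPKM in line a and 10.4 in line b in the authors' deposited table (log2 1.26, implied error 0.34), and CYP71Z7, a cytochrome P450 of the same gene cluster, at 2.81 and 6.71 (log2 1.26). CPS2, a diterpene cyclase in a merged locus, had the largest deposited ratio and a wide error (2.32, implied error 1.44), and CPS4, of momilactone synthesis, stood at 4.94 and 9.17 (log2 0.89). AOS2, allene oxide synthase, was higher in line b (0.99). RAB16B, a dehydrin, went the other way, from 41.2 to 14.9 FPKM (log2 -1.47, implied error 0.36) in the authors' deposited table.

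Fewer loci were called here than in any comparison with wild type, 893 of 17876 (442 higher and 451 lower in line b), and 148 changed at least 2-fold. RAB16C (-1.03), WRKY76 (-0.81), LEA3 (-0.80) and CAB2R (-0.52) were the other named genes lower in line b by the deposited log2 ratios. Phytoalexin genes rose at 7 of 9, or 8 when adjusted over the list alone (Fisher's exact test, adjusted p = 8.55e-09), with KSL4 and MAS not called, and pathogenesis-related proteins at 3 of 5, or 4 when adjusted over the list alone (adjusted p = 0.00177). LEA proteins fell at 3 of 5 (Fisher's exact test, adjusted p = 0.00177) and photosynthesis genes at 5 of 12 (adjusted p = 1.57e-04). With the implied error as deposited 31 loci were called after median-centring and these list calls were lost (Fisher's exact test, adjusted p = 1.000 for phytoalexin, pathogenesis-related and photosynthesis genes, and 0.116 for LEA proteins). With adjustment within the comparison 264 loci were called, so most of the 893 calls rest on the adjustment over all comparisons together.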

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

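The tests of the wild-type move, the growth boxes, library scaling and imprecise values were chosen only after the results were seen, and the test on time of day before.

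Of the 75 named genes, 20 were called between the knockout lines by the deposited q, 11 of them higher in line b and 9 lower. The deposited p is the test of the difference. The naming rule had taken 10 of the 20 as the most different between the lines, so this count is no rate. Over all loci 893 of 17876 (5.00%) were called, or 30 by the deposited statistic. The deposited q is adjusted over all comparisons together, and most of the 893 calls were lost with adjustment within this comparison. Among the 20, the deposited q ran from 0.000253 (KSL7 among others) to 0.0393 (ACO1). How many of the 20 remain with adjustment within the comparison was not counted, so they are calls by the pooled q only. The deposited log2 ratios of line b over line a were 2.32 for CPS2, 1.26 for KSL7, 1.26 for CYP71Z7 and 0.89 for CPS4, all of diterpenoid synthesis. The defence genes PBZ1, PR5 and CHT1 stood at 0.77, 0.62 and 0.33, the regulator WRKY71 at 0.38, and the jasmonate gene AOS2 at 0.99. NIA1, nitrate reductase, was at 0.66, and ACO1, which makes ethylene, at 0.50. Among genes lower in line b, the dehydrins RAB16B and RAB16C stood at -1.47 and -1.03, LEA3 at -0.80 and WRKY76 at -0.81. The photosynthesis genes CAB2R, RCA, PSAH, PSBW and PETE stood at -0.52, -0.38, -0.35, -0.32 and -0.29.

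Photosynthesis genes lower in both knockout lines than in 12-day wild type are the first pattern weighed. A scaling error between libraries is argued against, since the lowest bound (ratio less 2 implied errors) of any primary wall cellulose gene was -0.60 while the photosynthesis median was -2.69. Against 5-day plants, harvested before the move of day 7, the medians were -2.34 in line a and -2.65 in line b. The median implied error per gene was 0.222 in line a. These medians argue against a rise of the moved wild-type plants above their 5-day level as the whole cause. Whether unmoved wild-type plants would have fallen by day 12 cannot be told, because none were sampled. Growth of the knockout plants in the closed boxes until day 12 cannot be told apart from genotype, as 0 wild-type groups were kept there that long. Harvest at another time of day also stays open. Of the clock genes tested in both lines 25% (1 of 4, exact interval 0.631 to 80.6) changed at least 2-fold in both, an interval too wide to decide. The prediction also asked LHY and PRR1, both clock genes, to change that much in opposite directions, which 1 changed gene cannot meet. Against 5-day wild type, where photosynthesis genes were also lower, 1 of 5 clock genes was called in both lines. Loss of OsC3'H1 function is the biological explanation the design names, and it may act alone or with these conditions.

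Defence genes higher in both knockout lines are the second pattern. Against 5-day wild type the WRKY medians were 2.68 in line b, with a median implied error per gene of 0.801, and 2.89 in line a. For these 4 loci, kept of 12, this argues against a fall of moved wild-type plants below their 5-day level as the whole cause. In both lines 3 of 4 WRKY and 3 of 5 pathogenesis-related loci were called higher there. Neither list passed its test by the deposited q, and both passed with the implied error as deposited. For the pathogenesis-related list that pass rests on the 3 members with a finite ratio, 2 of them not called by the deposited q. It is therefore no second test of the 3 of 5 above. Whether unmoved wild-type plants would show the rise by day 12 cannot be told. Growth in the boxes until day 12 cannot be told apart from genotype here either (0 wild-type groups in boxes until day 12). An effect of the knockout may account for the rise, alone or with growth in the boxes, which remains a hypothesis found on the same data.

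Diterpenoid phytoalexin genes higher in line b than in line a are the third pattern. Imprecise values of weakly expressed genes cannot be told apart from a real difference. The list median of 1.26 lay at percentile 99.995 of random lists matched on mean expression, but that ranks the ratios in which the pattern was seen. With the genes' own implied errors the list call was lost (adjusted p = 1.000 by Fisher's exact test, and 1.74e-08 to 1.000 over the alternatives), because the errors taken are larger while the ratios stay as they were. The lines are 2 separate knockout lines of the same gene, and no biological explanation was tested. A difference between the lines themselves, between individual plants or between growth boxes stays open.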

How the results depend on the processing

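The table's own significance mark (q under 0.1) and the restriction to loci with 1 annotated gene were chosen only after the data were seen. No ratio of a named gene changed sign and no list median was marked as reversed, but the alternatives run on these could hardly do so. Adding 1 to the FPKM keeps the sign of a gene's ratio. Centring subtracted medians of only -0.0128 to 0.00473. Counts and list tests were compared by size or by side of the threshold, so a reversal was not looked for there. Of the named genes' ratios 367 values stayed within their error and 1 moved (NIA1 in line a, -4.14 on log2(FPKM + 1)), and of the values for list tests past the threshold 73 stayed past it and 15 did not. These 15 fell on cell cycle, jasmonate, LEA, phytoalexin, pathogenesis-related, photosynthesis and phenylpropanoid lists, under the 2-fold minimum, the implied error, the adjustment within a comparison and, for photosynthesis genes between the lines, q under 0.01 (adjusted p 0.702). Of the values for list tests not past the threshold 981 stayed so and 35 passed, 21 with the implied error, 9 with the 2-fold minimum and 5 with q under 0.01. Flavonoid, LEA and nitrogen genes passed against 5-day wild type in both lines with the implied error (adjusted p 0.0222 and 0.0276, 0.0147 and 0.0198, 0.0356 and 0.0440), and iron genes with the 2-fold minimum (0.0293 and 0.0248). The LEA pass covers only the 3 of 5 tested members with a finite ratio. Of the 3 iron genes tested, 2 had a group listed at 0, and such infinite ratios pass any fold minimum. Pathogenesis-related genes between the lines had an adjusted p of 0.471 with adjustment within the comparison. Of the list medians 53 stayed and 1 moved (phytoalexin genes in line b against 12-day wild type, 2.29 on log2(FPKM + 1)). The restriction to 1 FPKM removed no tested locus and so equals adjustment within each comparison.

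With a 2-fold minimum the counts for line a and line b against 12-day wild type were 3816 and 4036, against 5-day wild type 4582 and 4849, between the wild types 1203, between the lines 148, in both lines against 12-day wild type 3300, and against both wild types 2367, since fewer loci can pass. In the same order, median-centred ratios tested with the implied error gave 4268, 4434, 5220, 5529, 1127, 31, 3821 and 2989, and a normal p from the deposited statistic gave 4276, 4437, 5223, 5533, 1115, 30, 3829 and 2993. These are fewer because the errors taken are larger at the typical locus and loci with a group at 0 drop out. Of the pairwise calls from the statistic, 4192, 4343, 5137, 5430, 1104 and 30 were also deposited calls. Between the wild types the share of called loci higher at 12 days went from 52.3% to 73.6% with the 2-fold minimum, and to 68.9% and 67.8% in these other tests. A q under 0.01 gave 3239 between the wild types and 401 between the lines. Between the lines the count was 264 with adjustment within the comparison, 264 with the 1 FPKM minimum and 1434 with the table's own mark. The correlation of the lines was 0.964 on log2(FPKM + 1), and 0.787 and 0.769 without a shared library, where 1 line is also set against a wild type of another age and medium, so the cause was not tested. The place between the wild types was 0.0467 in line a and 0.0423 in line b over all called genes, and the cause was not tested. Lists past the threshold in both lines against 12-day wild type numbered 9 with the implied error and 5 as reported, the added ones being phenylpropanoid, nitrogen, low oxygen and LEA genes, and the cause was not tested.

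No paired analysis was possible because the table holds 1 value per group. For the same reason it was not possible to leave out a replicate in turn, to fit a replicate block or to count other splits of the samples. Depth is unknown, so a listed 0 sets no upper limit.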

Other observations

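The tests on chlorophyll synthesis and breakdown were set down before their results were seen, on lists written after other values had been seen.

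Genes of chlorophyll synthesis fell with the photosynthesis genes, at 8 of 8 members in both lines against both wild types. The list medians were -1.64 in line a and -1.95 in line b against 12-day wild type and -2.04 and -2.20 against 5-day wild type (Fisher's exact test, adjusted p = 5.59e-05, 6.93e-05, 1.33e-04 and 1.49e-04, in a family of the 3 added lists). CHLH and CHLI, subunits of the magnesium chelatase that opens the chlorophyll branch, stood at 226 and 292 FPKM in 12-day wild type, 63.3 and 84.8 in line a, and 52.9 and 69.9 in line b of the authors' deposited table. PORA, which reduces protochlorophyllide in the light, went from 581 FPKM at 5 days and 222 at 12 days to 58.9 and 44.5 in the knockouts by the deposited values. Between the wild types 5 of 8 were lower at 12 days (Fisher's exact test, adjusted p = 0.0105). CHLH, CHLI and PORA were picked as examples from the list after its values were seen.

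Chlorophyll breakdown genes went both ways. SGR, which takes part in dismantling chlorophyll in ageing leaves, rose from 5.21 FPKM at 5 days and 10.7 at 12 days in wild type to 61.7 in line a and 73.8 in line b in the authors' deposited table. NOL, a chlorophyll b reductase, was lower in the knockouts, at 23.4 and 22.4 FPKM beside 35.3 in 12-day wild type, and NYC1, another, was not called. Clock genes passed no list test in any comparison, and against 12-day wild type 2 of 4 tested were lower in line a and 3 higher and 2 lower of 5 in line b. The test takes each direction on its own, so a list that moves both ways can hardly pass it. Among them LHY, a morning-expressed factor, stood at 515 FPKM in 12-day wild type and at 137 and 92.1 in the knockouts by the deposited values, while 153 in 5-day wild type. Of the loci without a name, Os11g0702100 went from 0.463 FPKM in 12-day wild type to 77.8 and 76.5 in the authors' deposited table, and Os08g0139700 from 933 to 4.03 and 2.96, with 0.866 in 5-day wild type.

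The first hypothesis was that chlorophyll synthesis falls with the photosynthesis genes, which would need most members called lower in both lines against both wild types. The count was 8 of 8 members of chlorophyll synthesis, in line with it. The other was that genes of chlorophyll breakdown rise, and 1 of 3 members was called higher, so the list as a group did not bear it out. SGR alone may still mark a loss of chlorophyll, which was not measured here.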
